A study of Mus musculus with 6 samples.

How the data were processed

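Messenger RNA was sequenced from mammary tumor cells of MMTV-PyVT mice, a transgenic line in which the polyoma middle T oncogene is expressed in the mammary epithelium. All mice were of the FVB/NJ strain, and the libraries were labelled either as wild type for Nr4a1 or as knockout. Per the labels' protocols, RNA was purified on columns, libraries were made with a NEBNext Ultra kit and 150-base paired-end reads were collected on a NovaSeq instrument. Each group had 3 libraries. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The disrupted part of the Nr4a1 allele is not given in the sources used here.

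The authors deposited 1 table of raw read counts per gene symbol, with 1 column per library and no normalization. The submitters' processing notes name CASAVA 1.8, HISAT2, featureCounts and the mouse genome build GRCm38 (mm10). The annotation release and the rules for strand and for reads with several alignments are not given in the sources used here. Reads shared by near-identical gene copies, or by overlapping genes on opposite strands, therefore cannot be assigned with certainty. The table lists 10995 rows. The highest count of each listed gene was at least 133, so genes with low counts had been removed by a rule that is not given in the sources used here, and genes outside the table were not analysed here. Symbols were matched to the GENCODE M21 annotation of GRCm38. Of the symbols, 10917 matched 1 gene, 17 matched more than 1 and 60 matched none, and 1 symbol stood on more than 1 row. In 16 rows the symbol had been turned into a date, as spreadsheet programs do, and those rows were kept as unnamed features.

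Total counts per library ranged from 19569173 to 24188875. Counts were analysed with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM scaling, the robust quasi-likelihood fit and its F test, with the group as the only term and Benjamini-Hochberg adjustment at 0.05. The filter removed 0 genes. Levels are given as CPM, counts scaled to the TMM-adjusted library size. Log2 fold changes are the libraries labelled knockout over those labelled wild type with the standard error (SE) of the fit. For Nr4a1 an exact permutation test of log2 CPM was added, whose smallest possible p is 0.1 for 3 libraries against 3. Gene lists were tested on log2 CPM (prior count 2) with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 listed members. Camera was also run with the correlation estimated for each list, and fry was used to describe each list's own movement. DESeq2 1.42.0 and limma-voom were the other tests of single genes.

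The test, the 42 gene lists (26 programmes and 16 sets of cell type markers), the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Nr4a1 and its family, Fos, Jun and Egr1, the 8 genes with the largest change in each direction past the threshold, and up to 4 such members of each called list. Where fewer than 8 passed, it named the 3 with the smallest unadjusted p in each direction, as values that did not pass. Since 0 genes passed, other genes were named after their values were seen. These were the 8 per direction with the largest fold change among the genes that DESeq2 called and whose groups did not overlap, leaving out unnamed gene models, members of called lists with the smallest unadjusted p, and members that passed when adjusted over their list alone. The features named in the additional observations were also chosen after their values were seen. Alternatives covered the scaling, the filter, the replicate number as a block, each library left out, the test, the threshold and the list correlation.

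The tests were checked on simulated counts for the 10995 genes, drawn with each gene's mean and spread in these libraries and with 200 genes changed. The edgeR test recovered 72% of 2-fold and 96% of 4-fold changes with 15 false calls, and DESeq2 recovered 84% and 99% with 63 false calls. The list test called the changed list, and 6 of 200 unchanged lists reached an unadjusted p under 0.05. Genes were drawn independently there, whereas members of some real lists moved together. The estimated correlation was 0.69 for macrophage and 0.71 for fibroblast markers. The simulation therefore could not check how often the list test calls correlated lists falsely. Nor did it hold a shift shared by many genes of 1 library, such as the one that set apart wild type replicate 1. Its shares of recovered changes may therefore not hold in these libraries, and 0 calls in edgeR do not exclude changes of that size. Overlap of sequence between genes was measured with Python 3.11.15 as the share of 31-base words in a gene's longest annotated transcript that occur, on either strand, in transcripts of another gene.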

Results

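Gene expression was measured in mammary tumor cells of MMTV-PyVT mice in 3 libraries labelled wild type and 3 labelled Nr4a1 knockout. Nr4a1 encodes an orphan nuclear receptor that is induced as an immediate early gene. The libraries labelled wild type held 21355333, 21637113 and 21221467 counts (replicates 1, 2 and 3), and those labelled knockout held 24188875, 23706415 and 19569173. No pair of libraries differed by as little as counting noise, since the smallest chi-square per degree of freedom between any pair was 23.3. The first principal component carried 60.1% of the variance of log2 CPM and set apart wild type replicate 1, at -51.3, from the other libraries, which lay between -2.22 and 28.8.

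The Nr4a1 transcript was not lower in the libraries labelled knockout. Nr4a1 (ENSMUSG00000023034.7, chromosome 15, 101254269 to 101274795, plus strand, GRCm38) had 711, 406 and 358 counts in the libraries labelled wild type and 612, 847 and 746 in those labelled knockout. Its mean level was 23.3 CPM ± 9.69 (SD, n = 3) with the wild type label and 32.8 CPM ± 6.70 (SD, n = 3) with the knockout label. The log2 fold change was 0.49 (SE 0.32, edgeR adjusted p = 0.59), and the two-sided exact permutation test gave p = 0.20, where 0.1 is the smallest value possible. Counts for the whole gene do not show whether the reads cover the disrupted part of the allele. The transcript goes against the labels if the allele gives no RNA, and it checks nothing if RNA persists. Every direction given here is therefore between libraries as labelled. The related receptor Nr4a2 stood at 8.41 CPM ± 4.27 (SD, n = 3) and 4.63 CPM ± 0.208 (SD, n = 3), with all 3 libraries labelled knockout below all 3 labelled wild type. Its log2 fold change of -0.86 did not pass (SE 0.36, edgeR adjusted p = 0.57). Without wild type replicate 1 it was -0.36 and that of Nr4a1 0.88, and without wild type replicate 3 that of Nr4a1 was 0.31. Nr4a3 was not among the listed genes and was not analysed here.

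**Figure D1:**
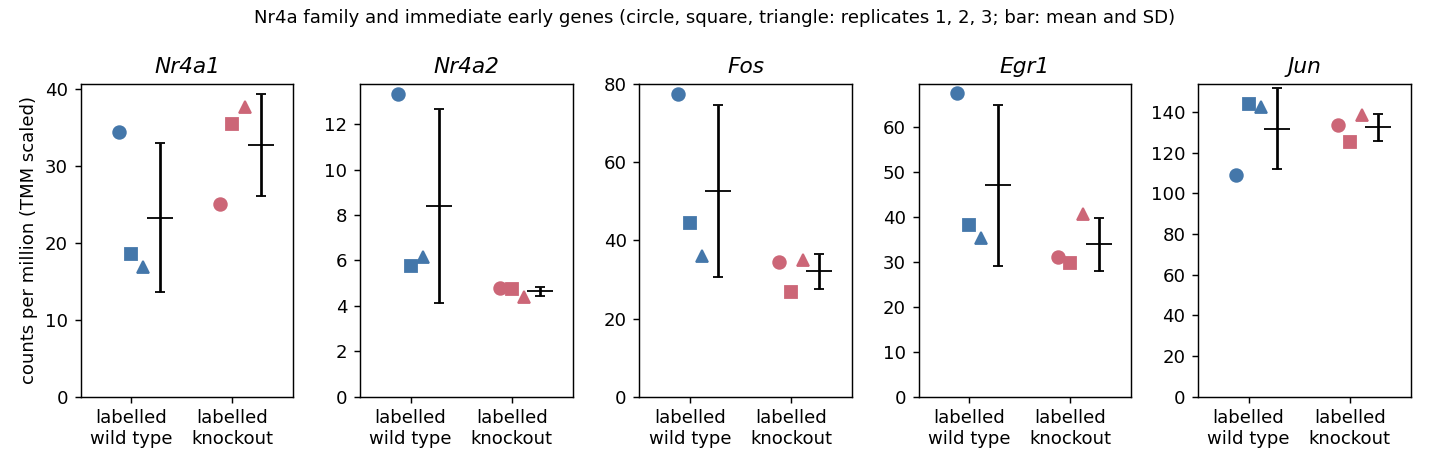
Expression (CPM) of Nr4a1, Nr4a2, Fos, Egr1 and Jun in each library, by group label, with points for the replicates and bars for the mean and SD. Nr4a1 averaged 23.3 CPM in the libraries labelled wild type and 32.8 CPM in those labelled knockout, and wild type replicate 1 had the highest Nr4a2, Fos and Egr1.

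The comparison asked which transcripts differ between tumor cells labelled knockout and those labelled wild type for Nr4a1. Among genes whose groups did not overlap, Ednrb, Fabp4, Rgs5 and Rgs4 had the highest fold changes towards the knockout label. Ednrb, an endothelin receptor, stood at 0.435 CPM ± 0.342 (SD, n = 3) in the libraries labelled wild type and 17.3 CPM ± 5.81 (SD, n = 3) in those labelled knockout, a log2 fold change of 5.29 (SE 0.54). Fabp4, a fatty acid carrier of fat cells and capillaries, stood at 3.14 CPM ± 0.982 (SD, n = 3) and 50.6 CPM ± 25.9 (SD, n = 3). Rgs5 and Rgs4, regulators of G protein signalling, had log2 fold changes of 2.71 (SE 0.48) and 2.43 (SE 0.26). In the other direction, leaving out unnamed gene models, Fam107a had a log2 fold change of -4.66 (SE 0.77). Evpl, which encodes envoplakin of the epithelial barrier, and the kallikrein Klk8 had -1.62 (SE 0.48) and -0.95 (SE 0.14), with Evpl at -0.92 without wild type replicate 1. Klk8 shares 27.2% of the 31-base words of its transcript with other genes.

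None of these passed the edgeR test, which called 0 genes higher and 0 lower among 10995; its smallest adjusted p was 0.273. At an unadjusted p under 0.05 it gave 866 genes, 407 higher and 459 lower, where 550 would be given by chance. That count was 1365 without wild type replicate 2, 513 without knockout replicate 1 and 388 without knockout replicate 2, and scaling by library size alone gave 455 higher and 397 lower. DESeq2 called 64 genes higher and 39 lower, and limma-voom called 0 and 0 with a smallest adjusted p of 0.38. All 103 DESeq2 calls had an edgeR unadjusted p under 0.05, and in 99 of them the groups did not overlap. Over all genes the groups did not overlap for 17.4%, where chance gives 10%. Without wild type replicate 2, edgeR called 1 gene higher, Apoe, and 1 lower, the unnamed gene model Gm13394, which shares 97.5% of its words with other genes, and it called 0 with any other library left out. DESeq2 shared 71 of its 103 calls without wild type replicate 1 and 33 without knockout replicate 2. It called 250 higher and 168 lower without wild type replicate 2, 92 and 75 without knockout replicate 3, and 38 and 44 without wild type replicate 3. It called 29 and 28 without knockout replicate 1, and 25 and 11 without knockout replicate 2.

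The genes with the smallest unadjusted p that were higher with the knockout label were Ednrb (edgeR adjusted p = 0.273), Rgs4 (0.273) and Cyp26b1 (0.287), which encodes a retinoic acid hydroxylase and stood at 24.7 and 54.1 CPM. Those lower were Rps27a (0.273), Klk8 (0.493) and Tmc4 (0.528). Rps27a, a ribosomal protein fused to ubiquitin, stood at 235 and 117 CPM, but 44.0% of the words of its transcript also occur in transcripts of other genes, so its reads are uncertain. Tmc4 shares 12.9% and Meis1 13.6%. DESeq2 called Ednrb (adjusted p = 3.52e-19), Fabp4 (2.86e-16), Rgs5 (7.44e-06) and Rgs4 (3.22e-14). Next in size, among called genes whose groups did not overlap, were Gucy1a1, a subunit of the nitric oxide receptor of smooth muscle, with a log2 fold change of 2.12 (SE 0.47), and Adgrf5 with 2.10 (SE 0.36). The homeobox gene Meis1 had 2.01 (SE 0.36) and the cytokine Il6 1.97 (SE 0.47) in the same test. The largest decreases among its calls without overlap, leaving out unnamed gene models, were those of Fam107a (-4.66, SE 0.71), Pglyrp1 (-1.65), Evpl (-1.61), Unc13d (-1.61), Hhipl2 (-1.46), Mal (-1.36), Megf6 (-1.24) and Gprc5a (-1.21), with adjusted p between 7.73e-08 and 0.0445.

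Markers of pericytes and smooth muscle, macrophages and fibroblasts, and mesenchymal genes, stood higher on average in the libraries labelled knockout. Among these lists, only the pericyte and smooth muscle list had mean levels that did not overlap between the groups. Outside them, the groups did not overlap either for the adhesion, luminal, hypoxia and glycolysis, NRF2, cholesterol and Schwann cell lists. The same held for the few listed endothelial and adipocyte markers. Wild type replicate 2 stood at 7.14 log2 CPM for the fibroblast list, against 6.81 and 6.95 in knockout replicates 1 and 3. For the mesenchymal list it stood at 7.94, against 7.89 and 7.87, and for the macrophage list at 4.85, against 4.72 in knockout replicate 3. Of the lists fixed before the data were examined, 33 could be tested, and camera at the preset correlation called 18 of them, 13 higher and 5 lower. With an estimated correlation it called 0, the smallest adjusted p being 0.475, and fry's test of movement in a single direction called 0 with a smallest adjusted p of 0.0903. Over all genes tested, edgeR called 0 members of any list. The pericyte and smooth muscle list had a median log2 fold change of 1.32 with 6 of 8 members above 0 (adjusted p = 0.000737, and adjusted p = 0.475 with an estimated correlation). Its mean level was 4.50 log2 CPM ± 0.50 (SD, n = 3) with the wild type label and 5.72 ± 0.35 (SD, n = 3) with the knockout label. When adjusted over the list alone, 5 members passed, namely Rgs5, Pdgfrb, Abcc9, Des and Myh11. The macrophage list had all 15 listed members above 0 and a median of 0.87 (adjusted p = 1.34e-07, and adjusted p = 0.492 with an estimated correlation). Its members include Mpeg1, a perforin-like gene of macrophages, at 38.7 and 70.0 CPM, and Lyz2, lysozyme, at 354 and 691 CPM, which shares 32.8% of its words with other genes. In this list 0 passed when adjusted over the list alone. All 13 fibroblast markers lay above 0, with a median of 0.76 (adjusted p = 0.00027, and adjusted p = 0.558 with an estimated correlation), and 0 passed when adjusted over the list alone. The list of mesenchymal transition and matrix genes had 24 of 28 members above 0 and a median of 0.74 (adjusted p = 1.25e-06, and adjusted p = 0.506 with an estimated correlation), with 0 passing when adjusted over the list alone. Postn, periostin, stood at 1159 and 2520 CPM, and Zeb2, a repressor of epithelial genes, at 25.4 and 49.3 CPM. The mean log2 fold change of the fibroblast list went from 0.68 to 1.15 without wild type replicate 2 and to 0.38 without knockout replicate 2. That of the mesenchymal list went from 0.62 to 0.40 without knockout replicate 2. The fibroblast median was 0.40 without wild type replicate 1, 1.16 without wild type replicate 2 and 0.40 without knockout replicate 2, and the mesenchymal median 0.46 without wild type replicate 1 and 0.40 without knockout replicate 2.

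Epithelial adhesion, luminal and squamous genes stood lower on average in the libraries labelled knockout. The epithelial adhesion list had 17 of 18 members below 0 and a median log2 fold change of -0.37 (adjusted p = 1.25e-06, and adjusted p = 0.492 with an estimated correlation), with 0 passing when adjusted over the list alone. The tight junction genes Cldn3, Cldn4 and Ocln had log2 fold changes of -0.76 (SE 0.20), -1.11 (SE 0.36) and -0.83 (SE 0.30). These were -0.54, -0.60 and -0.49 without wild type replicate 1. Luminal mammary markers had 10 of 11 members below 0 and a median of -0.50 (adjusted p = 0.00013, and adjusted p = 0.475 with an estimated correlation). Of these, 3 passed when adjusted over the list alone, the keratins Krt19 and Krt7 and the membrane protein gene Prom1. Krt7 stood at 886 CPM ± 91.7 (SD, n = 3) and 596 CPM ± 63.0 (SD, n = 3). All 5 listed squamous markers lay below 0 with a median of -1.82 (adjusted p = 0.00867, and adjusted p = 0.506 with an estimated correlation), and 0 passed when adjusted over the list alone. The mean level of the squamous list overlapped between the groups, at 4.11 log2 CPM in knockout replicate 3 against 4.06 and 3.80 in wild type replicates 1 and 3. The keratin Krt16 stood at 25.4 CPM ± 26.5 (SD, n = 3) and 7.24 CPM ± 4.31 (SD, n = 3), and it shares 51.9% of its words with other genes. Krt6a and Krt6b in the same list share 62.8% and 57.0%, and Krt6b differed 62.4 times between libraries labelled knockout. This list was no longer called without wild type replicate 2 (adjusted p = 0.102). The mean log2 fold change of the adhesion list went from -0.42 to -0.27 without wild type replicate 1, and that of the luminal list from -0.54 to -0.82 without knockout replicate 3. That of the squamous list went from -1.51 to -0.71 without wild type replicate 2 and to -2.74 without knockout replicate 3. The adhesion median was -0.25 without wild type replicate 1 and the squamous median -0.48 without wild type replicate 2.

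**Figure D2:**
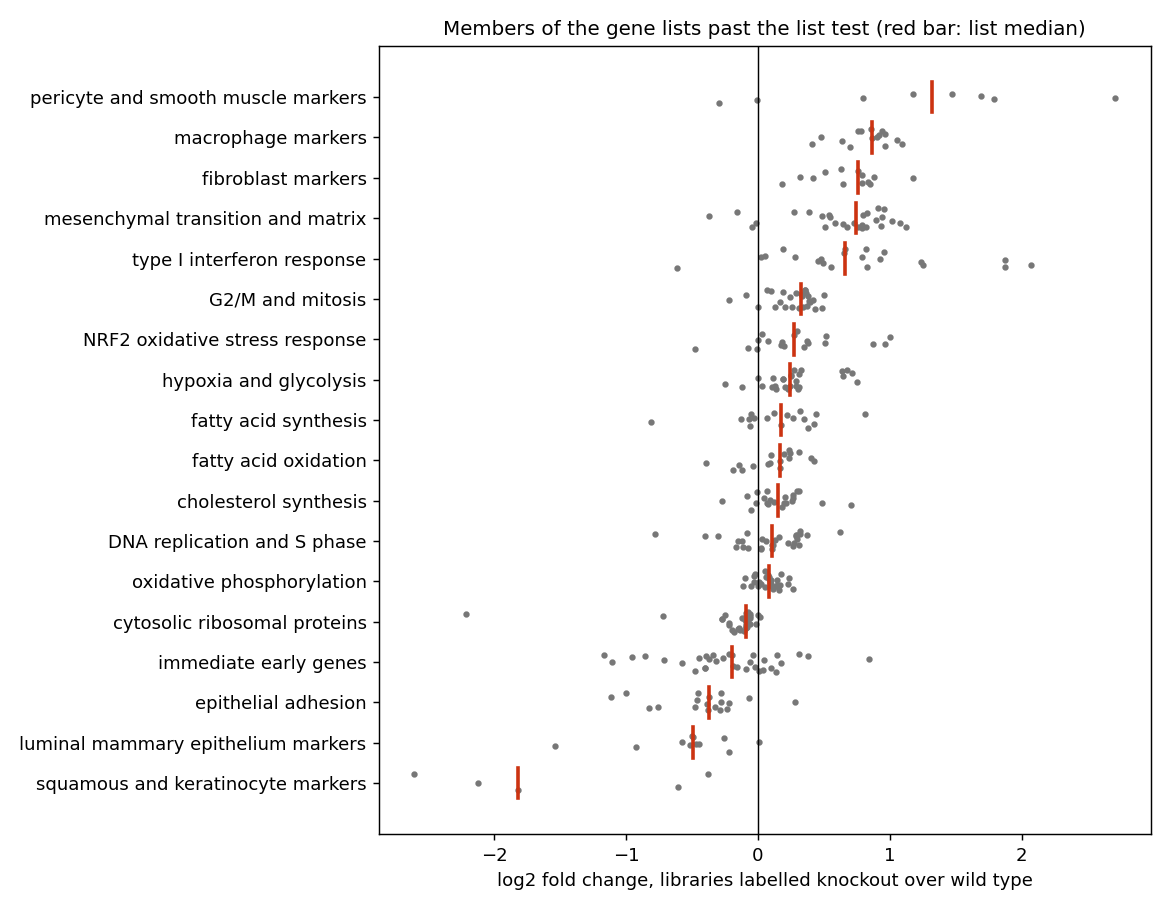
Log2 fold change, libraries labelled knockout over wild type, of each listed member (grey points) of the 18 gene lists called by camera at the preset correlation, with the list median as a red bar. The pericyte and smooth muscle list has the highest median, 1.32, and the squamous list the lowest, -1.82; 0 lists were called with an estimated correlation.

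**Figure D3:**
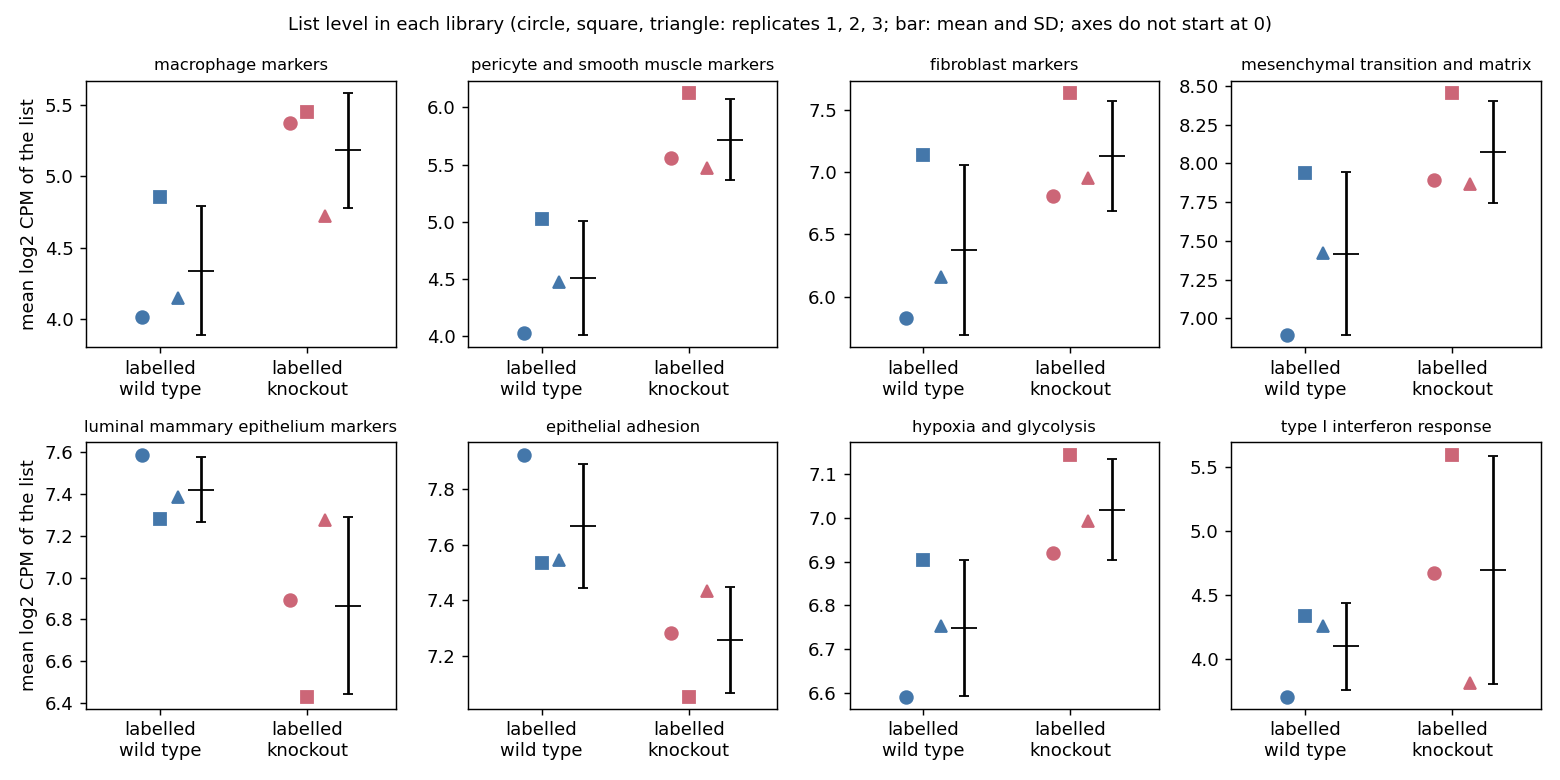
Mean log2 CPM of 8 lists in each library, with points for the replicates and bars for the mean and SD of each group; the axes do not start at 0. The pericyte and smooth muscle list is higher in every library labelled knockout than in every library labelled wild type. So is the hypoxia list, narrowly (lowest knockout 6.92, highest wild type 6.90). The adhesion and luminal lists are lower in every library labelled knockout (highest knockout 7.43 and 7.27, lowest wild type 7.53 and 7.28). The macrophage, fibroblast, mesenchymal and type I interferon lists overlap between the groups. The interferon list reaches 5.59 in knockout replicate 2 and 3.82 in knockout replicate 3.

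Lists of metabolism and stress defence were also called higher, by smaller amounts. Hypoxia and glycolysis genes had 26 of 28 members above 0 and a median log2 fold change of 0.25 (adjusted p = 1.25e-06, and adjusted p = 0.475 with an estimated correlation), with 0 passing when adjusted over the list alone. The lactate exporter Slc16a3 stood at 84.2 and 134 CPM, and Egln3, an oxygen sensor, at 5.19 and 8.10 CPM. The NRF2 list had 16 of 19 members above 0 and a median of 0.28 (adjusted p = 0.000297, and adjusted p = 0.492 with an estimated correlation), and 2 genes passed when adjusted over the list alone. Gclm, of glutathione synthesis, stood at 54.1 and 68.8 CPM, and Slc7a11, the cystine importer, at 10.7 and 21.3 CPM. The cholesterol synthesis list had 17 of 22 members above 0 and a median of 0.15 (adjusted p = 0.00126, and adjusted p = 0.475 with an estimated correlation), and 1 gene, the sterol sensor partner Insig1, passed when adjusted over the list alone (log2 fold change 0.70, SE 0.14). Fatty acid synthesis genes had 11 of 17 above 0 and a median of 0.17 (adjusted p = 0.00234, and adjusted p = 0.475 with an estimated correlation). The desaturases Fads2 and Fads1, which make polyunsaturated fatty acids and neighbour each other on chromosome 19, were the 2 genes that passed when adjusted over the list alone. Fads2 stood at 145 CPM ± 2.77 (SD, n = 3) and 197 CPM ± 3.75 (SD, n = 3), and fry found that the list changed in either direction (adjusted p = 0.000297). The fatty acid oxidation list had 12 of 17 above 0 and a median of 0.16 (adjusted p = 0.00717, and adjusted p = 0.499 with an estimated correlation). The oxidative phosphorylation list had 24 of 30 above 0 and a median of 0.084 (adjusted p = 0.0226, and adjusted p = 0.676 with an estimated correlation). In both, 0 passed when adjusted over the list alone. Without wild type replicate 3 or knockout replicate 3 the oxidation call was lost (adjusted p = 0.0785 and 0.0959). The oxidative phosphorylation call was lost without wild type replicate 1 (0.142), wild type replicate 3 (0.172), knockout replicate 2 (0.0518) or knockout replicate 3 (0.0538), the mean log2 fold change in the last 3 cases being 0.063, 0.064 and 0.072. The mean log2 fold change went from 0.27 to 0.17 for hypoxia and glycolysis without knockout replicate 2, and from 0.30 to 0.19 for NRF2 without wild type replicate 1. It went from 0.14 to 0.087 for fatty acid synthesis without knockout replicate 3, and for fatty acid oxidation from 0.10 to 0.17 without wild type replicate 1, 0.064 without wild type replicate 3 and 0.050 without knockout replicate 3. For oxidative phosphorylation it went from 0.075 to 0.047 without wild type replicate 1 and to 0.12 without wild type replicate 2. The medians of the NRF2, fatty acid synthesis and oxidative phosphorylation lists were 0.13, 0.32 and 0.047 without wild type replicate 1. The median of fatty acid synthesis was 0.26 without knockout replicate 2, that of fatty acid oxidation 0.081 without knockout replicate 3 and that of oxidative phosphorylation 0.13 without wild type replicate 2.

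Interferon, cell cycle, ribosomal and immediate early genes were called as lists, and their calls or the size of their shift changed with single libraries left out. The type I interferon list had 20 of 21 members above 0 and a median of 0.66 (adjusted p = 0.00135, and adjusted p = 0.676 with an estimated correlation). Isg15, a ubiquitin-like interferon target that shares 13.1% of its words with other genes, stood at 19.5, 74.0 and 5.65 CPM in knockout replicates 1, 2 and 3, and without knockout replicate 2 the mean log2 fold change of the list went from 0.75 to 0.17 (adjusted p = 0.288). The G2/M list had 25 of 27 above 0 and a median of 0.33 (adjusted p = 0.000297, and adjusted p = 0.676 with an estimated correlation). Its mean log2 fold change went from 0.26 to 0.082 without wild type replicate 1 (adjusted p = 0.0856) and to 0.49 without wild type replicate 3. The DNA replication list had 21 of 30 above 0 and a median of 0.11 (adjusted p = 0.0281, and adjusted p = 0.665 with an estimated correlation). It was not called without wild type replicate 1 (0.236), wild type replicate 2 (0.233), knockout replicate 1 (0.0641) or knockout replicate 3 (0.0974), and its mean of 0.082 went to 0.042 without wild type replicate 1, 0.054 without wild type replicate 2 and 0.17 without wild type replicate 3, and was 0.058 and 0.079 without knockout replicates 1 and 3. Ribosomal protein genes had 31 of 33 below 0 and a median of -0.091 (adjusted p = 0.00362, and adjusted p = 0.727 with an estimated correlation). Without wild type replicate 1 their mean log2 fold change went from -0.20 to -0.039 and the test pointed up (adjusted p = 0.802). Without knockout replicate 3 the mean was -0.18 at an adjusted p of 0.0538. Immediate early genes had 23 of 33 below 0 and a median of -0.20 (adjusted p = 0.00867, and adjusted p = 0.475 with an estimated correlation). Fos had a log2 fold change of -0.71 (SE 0.30), Egr1 -0.47 (SE 0.28) and Jun 0.0069 (SE 0.12), and none of the 3 passed (edgeR adjusted p = 0.574, 0.584 and 0.985). Their log2 fold changes were -0.33, -0.12 and -0.11 without wild type replicate 1. The mean of this list went from -0.23 to -0.12 without wild type replicate 1, which had the highest Fos. Without knockout replicate 3 it stayed at -0.22 at an adjusted p of 0.0538. In these 5 lists 0 genes passed when adjusted over the list alone. The medians were 0.10 for G2/M, 0.023 for ribosomal proteins and -0.13 for immediate early genes without wild type replicate 1. Without wild type replicate 3 they were 0.55 for G2/M, 0.19 for DNA replication and -0.16 for ribosomal proteins, which had -0.15 without wild type replicate 2, and the interferon median was 0.24 without knockout replicate 2.

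The other 15 tested lists were not called with all 6 libraries, and 5 of them were called with 1 library left out. Their adjusted p values were 0.0587 for Schwann cell markers (median log2 fold change -0.32), 0.0712 for basal and myoepithelial markers (0.43), and 0.106 for NF-kB and inflammatory mediators (-0.30). They were 0.259 for replication stress and DNA repair (0.051), 0.292 for MHC class I (0.097), and 0.363 for the unfolded protein response (0.0040). The Notch pathway gave 0.625 (0.23), milk proteins 0.626 (-0.29) and MAPK feedback 0.801 (0.044). Values were 0.825 for Wnt targets (0.14) and for the caspase and BCL2 family (0.037), and 0.847 for p53 targets (0.042). They were 0.925 for TGF-beta response (0.013) and for heat shock chaperones (0.030), and 0.979 for MYC targets (-0.0035). The test pointed down for the caspase list (mean -0.038) and for p53 targets (mean 0.0022), against their medians. It pointed up for heat shock chaperones, against their mean of -0.13. When adjusted over the list alone, 1 gene passed among Schwann cell markers, the adhesion gene L1cam. Among basal markers 1 passed, Mylk, the myosin light chain kinase of smooth muscle, and 0 passed in the other lists. The mean log2 fold change of 14 of these 15 lists, all but Schwann cell markers, moved by over 1.5 times or turned sign with some library left out. That of basal markers went from 0.46 to 0.17 without wild type replicate 1 and 0.70 without wild type replicate 2. That of the NF-kB list went from -0.12 to 0.086 without wild type replicate 3, and that of the Notch pathway from 0.20 to 0.41 without wild type replicate 2. That of replication stress genes went from 0.058 to 0.16 without wild type replicate 3 and -2.24e-05 without wild type replicate 1. With 1 library left out, Schwann cell markers were called lower without wild type replicate 1 (adjusted p = 0.0262) and knockout replicate 2 (0.00728). Basal markers were called higher without wild type replicate 2 (0.0162), knockout replicate 1 (0.0498) and knockout replicate 2 (0.0486). The NF-kB list was called lower without wild type replicate 2 (0.0145) and knockout replicate 3 (0.0363), p53 targets lower without wild type replicate 1 (0.0190), and replication stress genes higher without wild type replicate 3 (0.00582).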

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

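Of the alternatives, DESeq2 and the estimated correlation moved the counts of calls most. Over the named genes and single lists, leaving out settings that could change nothing, 1097 of 1193 other values kept their direction and their side of the threshold, 38 came to pass, 34 no longer passed and 24 turned direction. Most of these values belong to named genes. None of those genes passed in edgeR with all 6 libraries, so that side of the threshold was nearly fixed in advance. A change of size alone counted as kept. DESeq2 called 64 genes higher and 39 lower where edgeR called 0. In the simulation with each gene's own spread it made 63 false calls against 15 in edgeR, so its calls may include false ones. The cause of the gap in these data was not tested. Leaving out each library gave from 0 to 1 higher and from 0 to 1 lower in edgeR, the 1 in each direction without wild type replicate 2, and from 25 to 250 higher and 11 to 168 lower in DESeq2. RLE factors, library size alone and the replicate block kept 0 calls in edgeR, and limma-voom gave 0. The replicate number as a block kept 17 of the 18 lists called, lost DNA replication (adjusted p = 0.0642), gained basal markers (0.0332) and gave an Nr4a1 log2 fold change of 0.55. Same-numbered libraries deviated with correlations of -0.11, 0.35 and -0.25, so the numbers were not taken to pair them. By these deviations the replicate 2 libraries were each other's closest match across the groups. The same held for wild type replicate 1 with knockout replicate 3, and for wild type replicate 3 with knockout replicate 1. By log2 CPM itself, wild type replicate 2 correlated more closely with knockout replicate 1 (0.981) than with knockout replicate 2 (0.972). Whether any of these pairs share a source of variation was not tested. Having no filter or a stricter one removed 0 genes and tests nothing, nor do the stricter thresholds and the windows of 5 and 20 Mb around Nr4a1, since 0 genes were called. The lists called numbered 18 or 19 under the scalings, 14 to 18 with a library left out, 18 without genes that stand in more than 1 list (chosen after seeing the data), and 0 with an estimated correlation. High correlation alone does not account for that loss, since the estimate was 0.032 for fatty acid synthesis and 0.026 for immediate early genes. Schwann cell markers, with a negative estimate of -0.18, also went to a camera adjusted p of 0.475. The adjusted p values with an estimated correlation are therefore not a correction for correlation alone. Of the 18, 10 kept their call with each library left out. The Nr4a1 log2 fold change stayed between 0.31 and 0.88 with a library left out and 0.49 and 0.55 otherwise. The share of genes called near Nr4a1 was 10.1% at an unadjusted p under 0.05 (added later). The direction turned with a library left out, by camera or for the gene, for lists that were not called and for ribosomal proteins. The cause was not tested. The mean log2 fold change ranged from -0.27 to -0.039 for ribosomal proteins, -0.043 to 0.16 for MHC class I, and -0.87 to 0.35 for milk proteins. It ranged from -0.021 to 0.11 for MAPK feedback, 0.0079 to 0.23 for Wnt targets, and -0.12 to 0.059 for caspases. It ranged from -0.14 to 0.13 for p53 targets, 0.014 to 0.10 for TGF-beta response, -0.19 to -0.0088 for heat shock chaperones, -0.029 to 0.027 for MYC targets and -0.11 to 0.075 for Jun. It also turned for MYC targets with library size alone (0.021), for heat shock chaperones with the block (-0.11), and without genes in more than 1 list for caspases (-0.021) and p53 targets (0.051).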

Other observations

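The tests of 3 patterns below, other than the overlap of sequence between gene copies and the counts over splits of the libraries, were chosen after the results were seen.

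Several vessel and fat markers stood in lists with too few listed members to test. All 3 listed endothelial markers lay above 0, with a median log2 fold change of 1.39, and 2 passed when adjusted over the list alone. Flt1, a VEGF receptor, stood at 25.3 CPM ± 10.1 (SD, n = 3) and 66.1 CPM ± 33.8 (SD, n = 3), and the adhesion gene Esam at 3.70 CPM ± 1.24 (SD, n = 3) and 13.3 CPM ± 3.91 (SD, n = 3). Of 4 listed adipocyte markers, 3 lay above 0 and 2 passed when adjusted over the list alone, Fabp4 and the lipoprotein lipase gene Lpl, at 13.7 and 35.2 CPM; the list median was 0.73. MHC class II (2 listed) had a median of 0.42, neutrophil markers (3 listed) a median of 0.43 with a mean of -0.40, skeletal muscle markers (2 listed) 0.44 and dendritic cell markers (1 listed) -0.059. The medians of MHC class II, neutrophil and skeletal muscle markers were 0.25, 0.13 and 0.23 without wild type replicate 1. For T and NK cell, B cell and erythroid markers 0 were listed. The homeobox gene Hoxb4, chosen after its values were seen, stood at 7.20 CPM ± 3.11 (SD, n = 3) in the libraries labelled wild type and 27.8 CPM ± 6.49 (SD, n = 3) in those labelled knockout. Its log2 fold change of 1.95 did not pass (SE 0.35; edgeR adjusted p = 0.574).

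Stromal and vascular markers stood higher on average in the libraries labelled knockout, and a lower share of epithelial tumor cells would raise all other cell types alike. The gap between the pericyte and fibroblast lists (shared genes left out) moved towards the pericyte list by 0.50 log2 units (SE 0.17) in the libraries labelled knockout, with no overlap between the groups. Fibroblast genes had the higher level with the wild type label, 6.37 against 4.24 log2 CPM. That baseline could hide part of their shift if tumor cells also express these genes, which was not tested. Schwann cell markers stood lower, at 6.02 ± 0.054 against 5.71 ± 0.14 log2 CPM (SD, n = 3), but their most abundant gene, Sox10 (353 and 283 CPM), is also expressed by mammary epithelial cells, so a lower epithelial share cannot be told apart from a change in pericytes. Without wild type replicate 1, 84.6% of the mean log2 fold change of the pericyte list stayed, and the levels still differed by 0.98 (SE 0.34). That library therefore did not make most of the pericyte shift. The macrophage, fibroblast and mesenchymal lists kept at least 67.7% but differed by less than 2 SE, at 0.68 (SE 0.42), 0.48 (SE 0.55) and 0.39 (SE 0.32). The part of wild type replicate 1 in these 3 lists stays open. These SE rest on only 2 libraries labelled wild type, where 2 SE is a loose bar. An effect of the genotype also stays open and was not tested apart from these.

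The Nr4a1 transcript was not lower in the libraries labelled knockout. An exchange of the 2 groups' labels, with an allele that gives no transcript, would leave the libraries labelled wild type without Nr4a1, and the lowest of them held 16.8 CPM. Transcript that persists from the disrupted allele could account for the level, but counts over the whole gene (log2 fold change 0.49) cannot show where reads fall, and this cannot be told apart from an intact gene. Around Nr4a1, where a knockout made in another strain may carry flanking sequence, edgeR called 0 of 109 genes within 10 Mb and 0 of 10807 elsewhere; at an unadjusted p under 0.05, chosen after the data were seen, the counts were 11 (10.1%) and 851 (7.87%), with a two-sided Fisher's exact p of 0.371.

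Some features differed over 10 times between libraries of the same group, in 50 of the listed genes. The unnamed gene model Gm13394 stood at 194, 3.49 and 188 CPM in the libraries labelled wild type and at 1.81, 2.64 and 2.12 CPM in those labelled knockout, and Gm12366 at 80.0, 64.6 and 8.99 against 0.985, 0.797 and 70.1 CPM. Reads shared between near-identical gene copies are a candidate explanation for part of them: for the 49 that match 1 gene, the median share of words found in other genes was 4.71%, above the 95th percentile (2.60%) of 1000 random sets of listed genes, whose median was 0.821%. Over 50% of the words were shared in 8 of the 49, and in 4.65% of 2000 other listed genes drawn at random. Most of the 49, such as the interferon gene Isg15, therefore stay open, and no biological explanation was tested. Gapdh, a gene with many processed copies, stood at 131 and 106 CPM in the replicate 2 libraries and between 15.0 and 16.5 CPM in the other libraries.

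The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. In edgeR all 10 splits gave 0 genes, and at an unadjusted p under 0.05 the real split gave 866 and the highest other 1011. For lists called at the preset correlation, 1 split gave as many as the real one, namely the real one itself, with 18 lists. Every split that mixed the labels also called lists, from 8 to 15 of them. A call at the preset correlation therefore does not by itself tie a list to the labels. For DESeq2, 2 splits gave as many as the real 103 genes, the highest other giving 118; it set wild type replicates 1 and 3 with knockout replicate 3 against the rest.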
